A study of Mus musculus with 4 samples.

How the data were processed

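The samples were 4 cultures of splenic CD8+ T cells from mice carrying the gBT-I transgenic T cell receptor, which recognises a herpes simplex virus peptide. Splenocytes of 2 mice were activated with peptide-pulsed cells and LPS and grown in IL-2. One culture of each mouse received 0.5 mM sodium butyrate and another received PBS from day 3 to day 5. Viable CD8+Vα2+ cells were sorted and captured on day 6 with 10x 3' v3.1 chemistry. The groups therefore hold 2 libraries each, all from batch 1, and the replicate number stands for the mouse.

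The deposited matrices hold UMI counts per gene and droplet barcode for 32285 genes and 6794880 possible barcodes per library, with no cell filter applied. The submitters' processing notes name Cell Ranger 4, Seurat 4.3 and the mm10 genome. The annotation release behind the matrices, and whether intronic reads were counted, are not given in the sources used here. Of the gene IDs, 32235 were found in GENCODE M21 (GRCm38), which gave the coordinates. UMIs of close paralogues (granzymes, histones, class I genes) may be assigned to the wrong member, and this was not resolved.

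Library totals were 64388093 and 74891790 UMIs in the control libraries and 76522004 and 74844548 UMIs in the butyrate libraries. Cells were called with the OrdMag rule, which keeps barcodes with at least 10 percent of the 99th percentile of the UMIs of the top 3000 barcodes. This gave limits of 6600 and 6644 UMIs for control and 6525 and 6202 UMIs for butyrate. Barcodes with under 500 genes or at least 10 percent mitochondrial UMIs were left out, the latter removing 217, 295, 63 and 92 barcodes in the order control 1, control 2, butyrate 1 and butyrate 2. Scrublet called only 3, 2, 8 and 8 doublets in that order, so no cell was removed as a doublet. An alternative left out the 34, 55, 52 and 57 cells with the highest scores.

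UMIs of the kept cells were summed per library and tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr, robust quasi-likelihood F test, group as the only term). An adjusted p (Benjamini-Hochberg) under 0.05 counted as passing, and the standard error (SE) was the log2 fold change divided by the square root of F. The unit of replication is the culture, with 2 per group, each from a different mouse. The p-values draw on variation pooled over genes, so they do not measure a gene's own spread between 2 cultures. With only 2 mice, they do not carry over to other mice. Mice were not a term of the fit. The deviations of the libraries from their group means correlated weakly between cultures of the same mouse (correlation across genes 0.059, Spearman 0.053). With the mouse as a block, an alternative fit, the common coefficient of variation between libraries fell from 0.0405 to 0.0336. Variation shared by the cultures of a mouse is therefore not excluded. Levels are given as TMM-scaled CPM, with factors of 1.07 and 1.08 for control and 0.932 and 0.934 for butyrate.

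In all, 32 gene lists fixed beforehand and the cytosolic ribosomal genes were compared with all other genes by camera in limma 3.58.1 with a preset correlation of 0.01, and with a correlation estimated per list. A list needed 5 tested members, and adjustment was over the 32 tested lists. With an estimated correlation, camera has only the residual degrees of freedom of a fit to 4 libraries. Few lists could pass with so few, whatever their correlation. This setting therefore cannot decide whether a list result holds. The lists cover memory and stemness, effector function, inhibitory receptors, homing, IL-2 and STAT5 targets, glycolysis, fatty acid oxidation, the TCA cycle, nuclear and mitochondrial genes of oxidative phosphorylation, cholesterol synthesis, short-chain fatty acid receptors and transporters, histone deacetylases, acetyltransferases and readers, responses to histone deacetylase inhibitors, linker and variant histones, S and G2M phase, interferon response, class I presentation, apoptosis and p53, immediate early genes, heat shock and unfolded protein response, and naive state. Others hold markers of CD8, CD4 or regulatory and gamma-delta T cells, and of NK, B, myeloid, dendritic and erythroid cells. The ribosomal list was drawn by symbol, so it also holds 8 S6 kinase genes and 3 pseudogenes.

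Named genes were fixed by rule before the data were examined. They are the 10 largest increases and 10 largest decreases among passing genes with a mean of at least 20 CPM and no overlap between groups, leaving out predicted genes and receptor segments. Il7r, Tcf7, Gzmb, Klrg1, Cd44, Cdkn1a and Bcl2 were always named, as were up to 4 members of each list with the smallest p. For G1 cells and for the Il7r classes the rule took the 6 largest in each direction. Some genes that the rule names are not reported here.

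For values per cell, each kept cell was thinned at random to 8000 UMIs. Cells below this depth, 71 and 112 in control and 54 and 68 in butyrate, were left out of these values. The share of cells with an Il7r UMI, with its exact 95 percent binomial interval for counting error, was compared by an exact two-sided permutation test. With 2 against 2 libraries this exact test cannot go below p = 0.333. Free RNA can put UMIs into cells that lack a gene, and no other cell type was present in numbers that could serve as background. Phases were scored on the thinned counts with Scanpy 1.11.5, with G1 for cells whose S and G2M scores were both at or below 0. Counts of G1 cells and of S or G2M cells, and thinned counts of cells with and without an Il7r UMI, were summed per library and class, and differences between classes and groups were tested in edgeR with the library as a block.

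On simulated data with known changes, edgeR in the comparison of all cells found 38.8, 79.1 and 97.0% of genes changed by 0.25, 0.5 and 1 on the log2 scale, and 4.67% of its calls were false. DESeq2 1.42.0 found 19.4, 64.2 and 90.9%, with 0.855% false. The edgeR fit with the mouse as a block found the same shares as that without it, but no mouse effect was simulated, so this cannot judge the block. The test between phase classes found 50.7, 82.1 and 95.5%, with 6.75% false. False calls made up 5.56% in G1 cells, 1.47% in S or G2M cells and 5.41% between Il7r classes. All simulations used the coefficient of variation of the all-cell fit (0.0405), although it was 0.0516 in the G1 fit. Each changed 200 genes, as many up as down, far fewer than passed in the data. The shares of found and false calls therefore need not hold for the data. The remaining edgeR tests found fewer of the small changes. These shares were 4.48, 34.3 and 89.4% in G1 cells, 32.8, 74.6 and 93.9% in S or G2M cells, and 35.8, 74.6 and 100% between Il7r classes. They were 0, 37.3 and 80.3% for the difference of the effect between phase classes, and 2.99, 20.9 and 71.2% for the difference of the Il7r class effect between groups. Of 20 random lists, camera called 0. Members of a random list need not vary together as those of a list fixed beforehand may. This check therefore cannot decide whether the preset correlation was large enough. Alternatives covered scaling, test, count filter, mouse block, each library left out, cell calling, mitochondrial limit, doublets, free RNA, depth, thinning, phase limit and cell class. Free RNA was subtracted at an assumed 5% of each sum. The sizes of clusters were not compared, because clusters separated by group.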

Results

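Single-cell RNA was counted in activated gBT-I CD8+ T cells after 2 days in butyrate or PBS, with 2 libraries per group, each from a culture of 1 of 2 mice. Butyrate is a short-chain fatty acid made by gut bacteria that also inhibits histone deacetylases. The series concerns CD8+ T cells with CD127, the interleukin-7 receptor chain encoded by Il7r that marks memory precursors. Library totals ranged from 64388093 to 76522004 UMIs. After filtering, 2059 and 2632 control cells and 2560 and 2664 butyrate cells were kept.

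Kept cells had medians of 21793 and 20494 UMIs in control and 24816 and 23627.5 UMIs in butyrate. The mean of these medians was 21144 ± 919 against 24222 ± 840 UMIs (SD, n = 2, exact two-sided permutation p = 0.333). Median genes per cell were 4216 and 4103 in control and 4134.5 and 4042.5 in butyrate (exact permutation p = 0.667). Median mitochondrial shares were 4.89 and 4.91% in control and 3.93 and 4.13% in butyrate, and ribosomal shares were 30.7 and 29.8% against 32.2 and 31.4% (exact permutation p = 0.333 for ribosomal shares). Among barcodes with at least 1000 UMIs, 23.8 and 21.7% of control and 8.25 and 8.77% of butyrate barcodes exceeded the mitochondrial limit of 10%. A Cd8a or Cd8b1 UMI was found in 95.8 and 94.6% of control cells and 95.6 and 95.9% of butyrate cells.

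The first comparison asked which genes butyrate changed across all kept cells. The perforin gene Prf1, the granzyme genes Gzmb and Gzmk and the chemokine genes Ccl4 and Ccl5 rose. The cell cycle inhibitor gene Cdkn1a also rose. Tcf7, which encodes a transcription factor of stem-like and memory T cells, fell, as did the desaturase gene Fads2. Of 13487 genes tested in edgeR, 4861 were higher and 4818 lower under butyrate. The median log2 fold change of all genes was -0.0079, and scaling by library totals alone moved it to -0.21, with 3395 genes higher and 6710 lower.

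Prf1 (ENSMUSG00000037202, GRCm38 chromosome 10, 61297833 to 61304680) rose from 28.8 ± 2.97 to 615 ± 27.2 CPM (SD, n = 2), a log2 fold change of 4.41 (SE 0.07, edgeR adjusted p = 7.01e-13). Gzmb (ENSMUSG00000015437, chromosome 14, 56258838 to 56262260) rose from 2675 ± 72 to 9991 ± 43.1 CPM, by 1.90 (SE 0.04, adjusted p = 5.05e-14). Gzmk (ENSMUSG00000042385, chromosome 13, 113171608 to 113225908) rose from 1.97 ± 0.0570 to 69.5 ± 8.60 CPM, by 5.14 (SE 0.11, adjusted p = 1.11e-09). Ccl4 (ENSMUSG00000018930, chromosome 11, 83662584 to 83664683) rose from 2.499 ± 0.673 to 112 ± 14.6 CPM, by 5.51 (SE 0.22, adjusted p = 0.000335). Ccl5 (ENSMUSG00000035042, chromosome 11, 83525778 to 83530518) rose from 80.9 ± 30.1 to 1408 ± 117 CPM, by 4.12 (SE 0.41, adjusted p = 0.0109). Its adjusted p was 0.0899 without butyrate replicate 1 and 0.0928 without butyrate replicate 2. The other large increases were Mt3 (4.51), Ckb (4.42), Lta (4.22), Serpine2 (3.59), Selenom (3.58) and Pmepa1 (3.45).

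Tcf7 (ENSMUSG00000000782, chromosome 11, 52252371 to 52283014) fell from 30.3 ± 0.454 to 8.85 ± 0.803 CPM, a log2 fold change of -1.77 (SE 0.07, edgeR adjusted p = 6.5e-12). Fads2 (ENSMUSG00000024665, chromosome 19, 10062765 to 10101746) fell from 35.2 ± 5.06 to 5.03 ± 0.955 CPM (-2.81, SE 0.19, adjusted p = 0.00056). The glycolytic gene Aldoc fell from 46.9 ± 6.16 to 8.25 ± 1.91 CPM (-2.504, SE 0.23, adjusted p = 0.00536), with an adjusted p of 0.0629 when mice were a block. The other large decreases were St3gal6 (-2.32), Ifi203 (-2.24), Abcb1b (-2.21), Slfn2 (-2.06), Samd9l (-1.95), Elk4 (-1.92), Tespa1 (-1.87) and Cdkn1b (-1.87).

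Il7r (ENSMUSG00000003882, chromosome 15, 9505788 to 9530176) rose slightly, from 45.2 ± 2.21 to 54.1 ± 3.40 CPM, a log2 fold change of 0.26 (SE 0.05, edgeR adjusted p = 0.000575). With library totals alone it was 0.06 (adjusted p = 0.327), and with every cell thinned to equal depth it was -0.022 (adjusted p = 0.794). Cdkn1a (ENSMUSG00000023067, chromosome 17, 29090976 to 29100727) rose from 51.7 ± 2.36 to 220 ± 11.3 CPM, by 2.09 (SE 0.05, adjusted p = 1.34e-13). Bcl2, a survival gene, fell by 0.28 (SE 0.05, adjusted p = 0.000164). Klrg1 rose from 0.406 ± 0.289 to 1.47 ± 0.501 CPM (1.79, SE 0.49, adjusted p = 0.0221). The Klrg1 value was 2.85 without control replicate 2, and 1.48 with an adjusted p of 0.0722 under a mitochondrial limit of 5%. Cd44 did not pass (adjusted p = 0.993), except with library totals alone, where it was -0.20 (adjusted p = 0.0239).

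**Figure D1:**
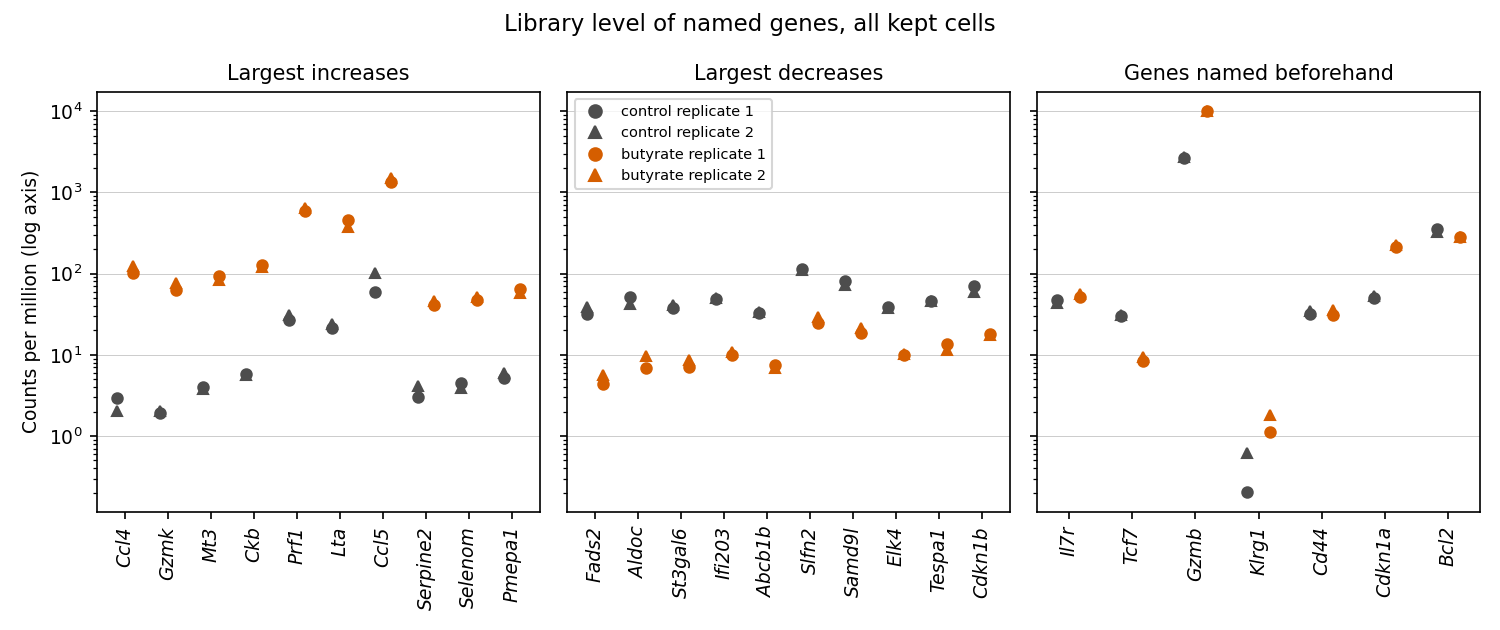
TMM-scaled CPM (log axis) of the named genes in each of the 4 libraries, grey for control and orange for butyrate, with circles for replicate 1 and triangles for replicate 2. Gzmb lay near 2675 CPM in control and 9991 CPM in butyrate, and Cd44 near 33.2 CPM in both groups.

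Effector genes carry out killing and cytokine release. Of 29 members tested, 20 rose and 1 fell, the same when adjusted over the list alone, with a median log2 fold change of 1.79 (camera adjusted p = 1.17e-16, adjusted p = 0.449 with an estimated correlation). Gzmc rose by 2.83 and Prdm1 by 1.88. Among 18 targets of IL-2 and STAT5, which drive effector growth, 16 rose and 1 fell, also when adjusted over the list alone (median 0.54, adjusted p = 3.82e-13, adjusted p = 0.449 with an estimated correlation). Il2ra rose by 1.35 and Osm by 1.74. Of 16 inhibitory receptor genes, 10 rose and 2 fell, as they did adjusted over the list alone (median 0.53, adjusted p = 0.0257, adjusted p = 0.449 with an estimated correlation). Havcr2 rose by 2.20, Nr4a2 by 1.88, Pdcd1 by 0.92 and Entpd1 by 0.89. The inhibitory list had an adjusted p of 0.0712 without control replicate 1 and 0.0741 without control replicate 2.

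Memory genes moved both ways. Of 22 memory and stemness genes, 10 rose and 9 fell, or 10 and 10 adjusted over the list alone, and the list did not pass (camera adjusted p = 0.451). Its median was -0.0033 and its mean 0.06, and the test pointed down. Cd27 fell by 1.44 and Satb1 by 1.31, while Foxo1 rose by 1.15. Of 20 naive-state genes, 8 rose and 9 fell, both over all genes and adjusted over the list alone (adjusted p = 0.314, median 0.02, mean 0.11, test down). Of 21 homing genes, 8 rose and 7 fell, with the same counts adjusted over the list alone (adjusted p = 0.463, median 0.0088). Ccr4 rose by 2.21 and Itgb7 by 0.75. With library totals alone the medians of the memory, naive and homing lists were -0.20, -0.18 and -0.19. Medians this close to 0 also changed sign when 1 library was left out. The memory median was 0.011 without control replicate 1 and 0.030 without butyrate replicate 1, the naive median -0.0099 without control replicate 2 and the homing median -0.075 without control replicate 1.

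Cholesterol synthesis supplies membranes for dividing T cells. Of 23 such genes, 1 rose and 21 fell, the same when adjusted over the list alone (median -0.57, camera adjusted p = 5.64e-09, adjusted p = 0.449 with an estimated correlation). Insig1 (ENSMUSG00000045294, chromosome 5, 28071363 to 28078662) fell from 49.4 ± 3.86 to 17.7 ± 0.112 CPM (-1.48). Stard4 fell by 1.00. Among 58 nuclear genes of oxidative phosphorylation, 36 rose and 8 fell, equally when adjusted over the list alone (median 0.22, adjusted p = 0.00667, adjusted p = 0.560 with an estimated correlation). Cox5a rose by 0.79 and Ndufb3 by 0.70. With library totals alone the counts for this list were 20 and 21 and its median 0.02.

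Other metabolic lists did not pass. Of 21 glycolysis genes, 2 rose and 11 fell, the same when adjusted over the list alone (camera adjusted p = 0.0535), with Pfkl at -1.14 and Tpi1 at -0.83. The glycolysis list passed without control replicate 2 (adjusted p = 0.0118), butyrate replicate 1 (0.0459) and butyrate replicate 2 (0.0119). Of 21 fatty acid oxidation genes, 8 rose and 7 fell, as adjusted over the list alone (adjusted p = 0.804, median -0.02, mean 0.14, test up), with Etfb at 0.97 and Hadha at -0.46. Of 31 TCA cycle genes, 13 rose and 17 fell, also adjusted over the list alone (adjusted p = 0.691), with Idh2 at 0.91 and Mdh2 at 0.63. Of 13 mitochondrially encoded genes, 1 rose and 7 fell, or 0 and 7 adjusted over the list alone (adjusted p = 0.266, and 0.0493 without control replicate 2). Among 7 genes that sense, carry or activate short-chain fatty acids, 2 rose and 2 fell, also adjusted over the list alone (adjusted p = 0.685, median 0.04, mean 0.03, test down). Its median was -0.16 with library totals alone, -0.0062 without control replicate 1 and -0.0022 without butyrate replicate 1. The receptor gene Ffar2 rose by 2.66, from 4 and 6 to 34 and 34 UMIs, and Acss1 fell by 1.72.

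Butyrate inhibits histone deacetylases. The list of deacetylase genes, which also holds sirtuin genes such as Sirt1, moved both ways. Of its 15 genes, 6 rose and 9 fell, also adjusted over the list alone (camera adjusted p = 0.463). Hdac1 rose by 0.98, while Sirt1 fell by 1.09 and Hdac5 by 0.88. Of 13 acetyltransferase and reader genes, 3 rose and 9 fell, as adjusted over the list alone (median -0.34, adjusted p = 0.00707, adjusted p = 0.449 with an estimated correlation). Kat2b fell by 1.38, Crebbp by 1.25 and Kat6b by 1.21. Of 13 genes that respond to deacetylase inhibitors, 10 rose and 2 fell, also adjusted over the list alone (median 0.66, adjusted p = 9.67e-05, adjusted p = 0.449 with an estimated correlation). Gsn rose by 1.70 and Gadd45b by 1.41. Of 19 linker and variant histone genes, 4 rose and 6 fell, the same adjusted over the list alone (adjusted p = 0.743), with H1fx at 3.57 and H2afx at -0.97.

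Genes of mitosis fell. Of 51 G2M genes, 4 rose and 44 fell, the same when adjusted over the list alone (median -0.60, camera adjusted p = 3.82e-13, adjusted p = 0.449 with an estimated correlation). Cdc20 fell from 134 ± 6.77 to 53.5 ± 2.23 CPM (-1.32), Cenpf by 1.23 and Cenpa by 1.01. Of 42 S phase genes, 17 rose and 13 fell, also adjusted over the list alone (adjusted p = 0.802, median 0.04). With library totals alone the S phase counts were 8 and 23 and the median -0.16. Rrm2 rose by 0.47 and Usp1 fell by 0.50. Of 22 apoptosis and p53 genes, 16 rose and 5 fell, as adjusted over the list alone (median 0.41, adjusted p = 0.00707, adjusted p = 0.485 with an estimated correlation). Zmat3 rose by 1.51 and Pmaip1 by 1.29, and Bbc3 fell by 0.79.

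Interferon genes mark antiviral signalling. Of 35, 5 rose and 22 fell, or 5 and 23 adjusted over the list alone (median -0.85, camera adjusted p = 1.3e-06, adjusted p = 0.729 with an estimated correlation). Ifi213 fell by 2.71 and Xaf1 by 1.62, while Zbp1 rose by 1.36. Of 16 class I presentation genes, 8 rose and 7 fell, the same adjusted over the list alone (adjusted p = 0.451, median 0.10, mean -0.11, test down), with Psmb10 at -1.02 and H2-Q7 at 0.78. The class I median was -0.10 with library totals alone. Of 17 immediate early genes, 9 rose and 4 fell, as adjusted over the list alone (adjusted p = 0.312), with Dusp2 at 1.70 and Btg2 at -0.68. Of 23 heat shock and unfolded protein genes, 16 rose and 5 fell, also adjusted over the list alone (adjusted p = 0.0719). This list passed without control replicate 1 (0.0486) and control replicate 2 (0.0118). Hspb1 had 0 and 1 UMIs in control and 265 and 258 in butyrate, Xbp1 rose by 0.85 and Trib3 fell by 1.07. Of 95 ribosomal genes, 71 rose and 5 fell, as adjusted over the list alone (median 0.28, adjusted p = 0.000523, adjusted p = 0.792 with an estimated correlation). Rpl27 rose by 0.59. With library totals alone the ribosomal counts were 42 and 16 and the median 0.08.

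Markers of other cell types were tested because sorted T cells can carry RNA of the stimulating splenocytes. Only genes with enough counts in at least 2 libraries were tested, 6 of 15 myeloid and 9 of 13 dendritic genes. Genes near 0 in control, such as Itgam and H2-Eb1, entered through the butyrate libraries, so these counts lean towards rises. The myeloid genes C1qa and C1qb had 0 UMIs in every library. Of 6 myeloid genes, 5 rose and 0 fell, as adjusted over the list alone (median 1.37, camera adjusted p = 0.00707, adjusted p = 0.449 with an estimated correlation). Itgam rose by 4.07, from 8 and 21 to 242 and 274 UMIs, and Cd68 by 2.37. Of 9 dendritic genes, 8 rose and 0 fell, also adjusted over the list alone (median 1.28, adjusted p = 0.0197, adjusted p = 0.458 with an estimated correlation). H2-Eb1 rose by 4.60, from 5 and 4 to 111 and 125 UMIs, and Fscn1 by 3.32. In cells called G1 neither list passed, with a median of 0.17 for 5 myeloid genes (adjusted p = 0.706) and 0.49 for 5 dendritic genes (adjusted p = 0.757). Of 6 CD4 or regulatory T cell genes, 4 rose and 2 fell, the same adjusted over the list alone (median 1.39, adjusted p = 0.0308, adjusted p = 0.560 with an estimated correlation). The adjusted p of this list was 0.230 without control replicate 1 and 0.341 without control replicate 2. Tnfrsf4 rose by 2.63 and Cd4 by 4.03, the latter from 3 and 1 to 33 and 40 UMIs.

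The remaining marker lists did not pass. Of 15 CD8 T cell genes, 3 rose and 7 fell, or 3 and 6 adjusted over the list alone (camera adjusted p = 0.552), with Cd8a at 0.45 and Trbc1 at -0.44. Of 5 gamma-delta genes, 2 rose and 1 fell, as adjusted over the list alone (adjusted p = 0.528, median 0.07, mean -0.10, test down), and the median was -0.13 with library totals alone and -0.011 without control replicate 2. Of 5 NK genes, 2 rose and 0 fell, also adjusted over the list alone (adjusted p = 0.0986). The NK list passed with mice as a block (0.00683) and without control replicate 2 (0.0335), butyrate replicate 1 (0.00178) or butyrate replicate 2 (0.0126). Tyrobp rose by 3.87, from 163 and 145 to 2180 and 2581 UMIs. Of 6 B cell genes, 4 rose and 2 fell, as adjusted over the list alone (adjusted p = 0.743, median 0.86, mean 0.71, test down), with Ighm at -1.72 and Fcmr at 1.22. Only 2 erythroid or platelet genes were expressed enough to test, too few for a list, and 1 rose.

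**Figure D2:**
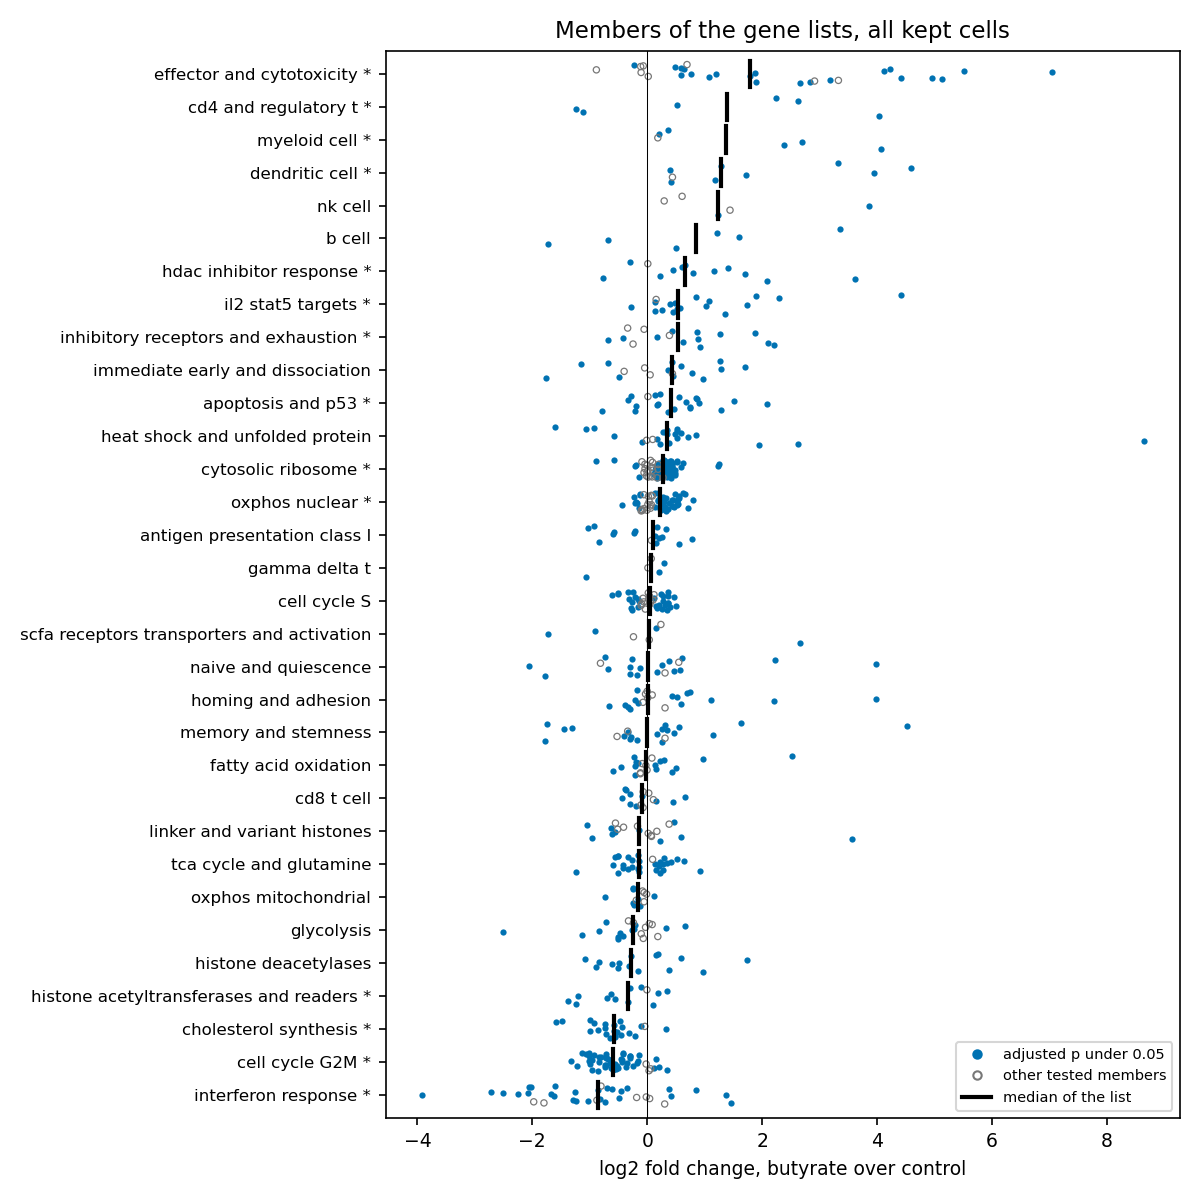
Log2 fold change (butyrate over control) of each tested member of the gene lists, filled where the edgeR adjusted p was under 0.05, with a bar at the list median and a star for lists passing with the preset correlation. The effector list had a median of 1.79 and the interferon list of -0.85, and the farthest point to the right is Hspb1, which had 0 and 1 UMIs in control.

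The next comparison asked whether butyrate changed the share of cells with Il7r transcripts. After thinning to 8000 UMIs per cell, 26.5% (exact 95% interval 24.5 to 28.5) and 24.9% (23.2 to 26.6) of control cells had an Il7r UMI. In butyrate the shares were 28.6% (26.8 to 30.4) and 30.1% (28.3 to 31.9). The difference of 3.68 points had an exact two-sided permutation p of 0.333, the smallest that 2 against 2 libraries allow. Mean Il7r UMIs per thinned cell went the other way, 0.532 and 0.502 in control and 0.415 and 0.472 in butyrate, a difference of -0.0732. The share difference itself depended on depth and on the count asked for. It was 10.2 points without thinning, 1.00 at 4000 UMIs per cell, -2.47 at 1000 UMIs with barcodes of at least 1000 UMIs, and -1.77 for cells with at least 2 Il7r UMIs. Within pair 1 it was 2.15 points. No other cell type could serve as background, and the B cell gene Cd79a was found in 0 and 0.0397% of control and 0.12 and 0.0385% of butyrate cells.

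Transcripts of Tcf7 were found in 17.6 and 17.0% of thinned control cells and 5.75 and 6.01% of butyrate cells. Gzmb was found in 96.1 and 96.3% of control cells and 99.8 and 99.7% of butyrate cells.

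Butyrate also shifted the phase scores, which rank cells by S and G2M genes. G1 calls made up 16.3 and 15.6% of control cells and 16.2 and 17.8% of butyrate cells, a difference of 1.07 points (exact permutation p = 0.667). The G1 difference depended on the score limit, and at a limit of 0.1 the shares were 21.03 and 20.6% in control and 29.5 and 30.5% in butyrate, 9.19 points apart (exact permutation p = 0.333). It was -0.0967 within pair 1 and 2.24 within pair 2, 0.701 without control replicate 2, 1.87 without butyrate replicate 1 and 0.274 without butyrate replicate 2. S calls made up 19.5 and 20.8% of control and 33.5 and 31.7% of butyrate cells, and G2M calls 64.2 and 63.7% against 50.3 and 50.5%. The difference in S calls was 12.4 points, and 5.92 at a limit of 0.1. Scores within 0.05 of the limit were held by 3.07 and 2.78% of control and 9.62 and 9.17% of butyrate cells. Free RNA can enter these calls, and they do not by themselves measure cycling.

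Effects of butyrate were then compared between cells called G1 and cells called S or G2M. Il7r fell in G1 cells and rose in S or G2M cells. Tcf7 fell in both, more so in G1 cells, and Gzmb rose in both. Il10 and Il24, cytokine genes of activated lymphocytes, and the lysosomal gene Cd63 rose in both. G1 cells lay mainly in cluster 0 in control (93.2 and 90.6%) and in clusters 6 (58.9 and 58.0%) and 4 (39.9 and 40.04%) in butyrate, so the classes hold different states.

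In G1 cells, 3198 genes were higher and 3132 lower of 10690 tested in edgeR. In S or G2M cells, 4734 were higher and 4722 lower of 13292. The effect differed between classes, with 2418 genes at a higher value in S or G2M cells and 2236 at a lower one. Both classes passed for 5174 genes, of which 570 moved in opposite directions. Il7r was at 184 and 167 CPM in control G1 cells and 79.6 and 83.8 CPM in butyrate G1 cells, a log2 fold change of -1.08 (SE 0.08). In S or G2M cells it was at 30.7 and 29.7 CPM in control and 45.6 and 48.8 CPM in butyrate (0.64, SE 0.05). Tcf7 changed by -3.09 in G1 and -1.45 in S or G2M cells, and Gzmb by 2.80 and 1.82. Il10 rose by 6.84 and 5.06, Cd63 by 5.75 and 6.50, Il24 by 5.72 and 2.15 and Il2ra by 2.08 and 1.25. The metallothionein gene Mt3 rose by 4.97 and 4.46. Esm1 rose by 5.19 and 3.32, the latter with adjusted p = 0.11 without butyrate replicate 1 and 0.109 without butyrate replicate 2. Aldoc fell by 3.78 and 2.13, the latter with an adjusted p of 0.081 with mice as a block.

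Lists in G1 cells followed a partly different order. S and G2M genes are not read here, because the class was chosen by their scores. Memory genes, which maintain long-lived T cells, fell, 14 of 21 with 3 rising, the same adjusted over the list alone (camera adjusted p = 4.63e-07, adjusted p = 0.375 with an estimated correlation), among them S1pr1 at -1.47. Naive-state genes fell, 15 of 19 with 1 rising, as adjusted over the list alone (adjusted p = 7.02e-11, adjusted p = 0.375 with an estimated correlation). Interferon genes fell, 24 of 31 with 5 rising, or 25 and 5 adjusted over the list alone (adjusted p = 1.49e-14, adjusted p = 0.164 with an estimated correlation), including Ifi206 at -3.15. Glycolysis genes fell, 15 of 21 with 2 rising, or 15 and 3 adjusted over the list alone (median -0.72, adjusted p = 6.41e-06, adjusted p = 0.378 with an estimated correlation). Heat shock and unfolded protein genes rose, 16 of 21 with 1 falling, as adjusted over the list alone (median 0.99, adjusted p = 1.13e-09, adjusted p = 0.375 with an estimated correlation). CD8 T cell genes fell, 11 of 15 with 3 rising, also adjusted over the list alone (median -0.46, adjusted p = 0.0104, adjusted p = 0.514 with an estimated correlation).

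Some lists that passed over all cells did not pass in G1 cells. The inhibitory receptor list had a median of 0.22 (camera adjusted p = 0.431), the acetyltransferase and reader list of -0.23 (adjusted p = 0.278) and the ribosomal list of 0.024 (adjusted p = 0.707). The histone gene H2afx was at -0.073 in G1 cells (edgeR adjusted p = 0.651).

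**Figure D3:**
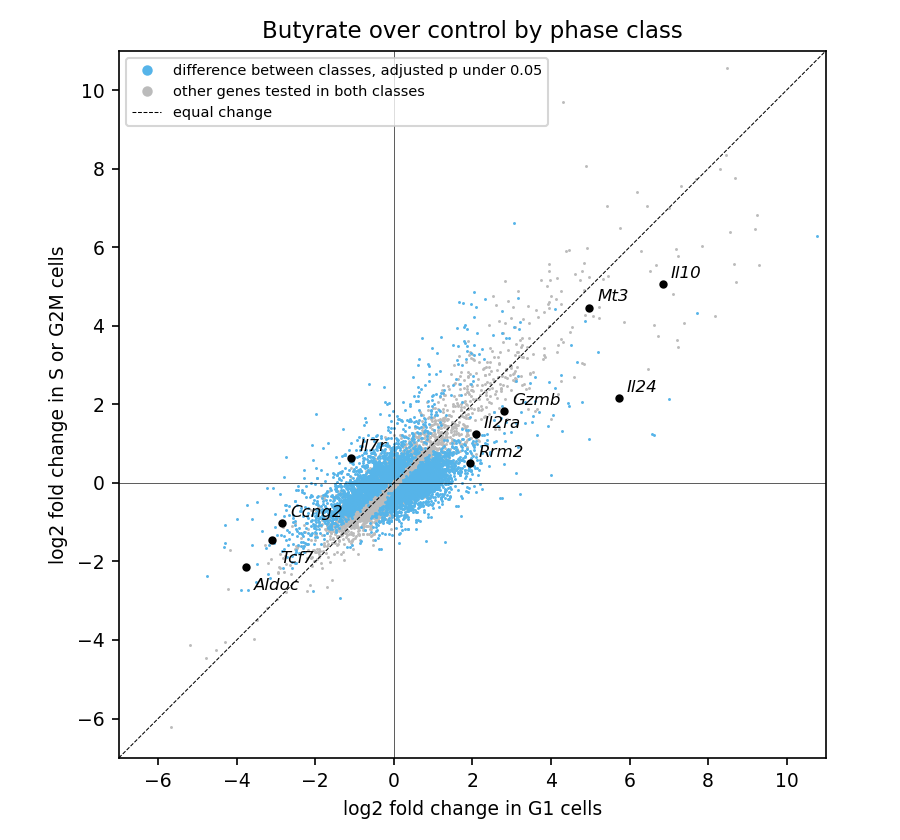
Log2 fold change (butyrate over control) in S or G2M cells against that in G1 cells for each gene tested in both classes, blue where the difference between classes passed in edgeR, with the dashed line at equal change. Il7r lies at -1.08 in G1 cells and 0.64 in S or G2M cells.

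**Figure D4:**
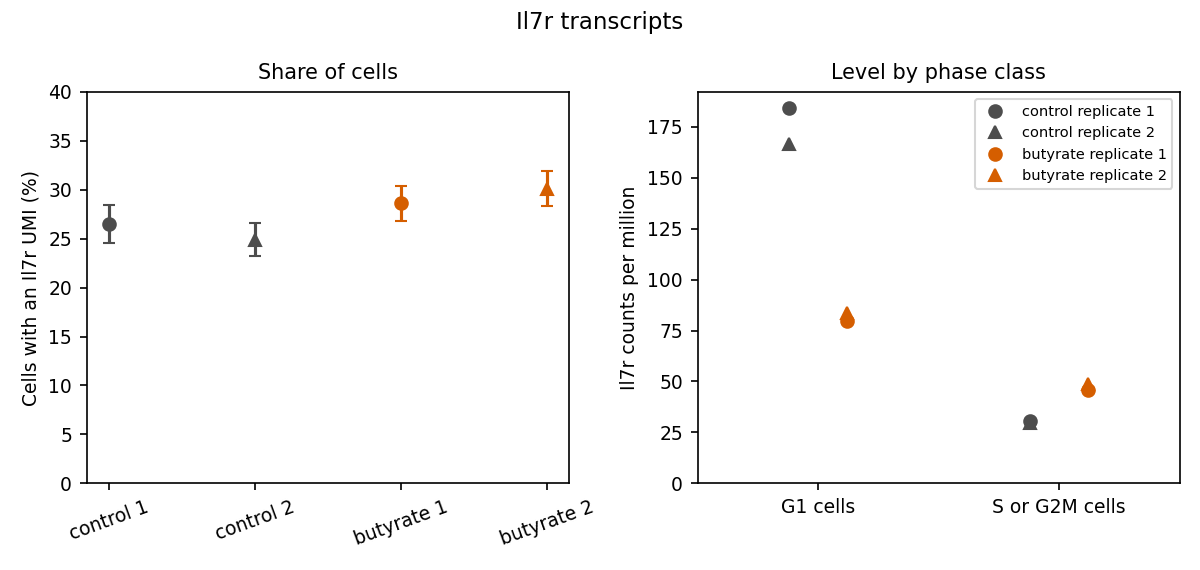
Left, share of thinned cells with an Il7r UMI in each library with exact 95% binomial intervals, and right, TMM-scaled Il7r CPM in G1 and in S or G2M cells of each library. The level in G1 cells was 184 and 167 CPM in control and 79.6 and 83.8 CPM in butyrate.

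The last comparison asked which genes went with Il7r transcripts within each culture. Cells with an Il7r UMI had more Tcf7 and Ccr7, genes of recirculating and memory cells, and more Gbp2 and Ifi214. They had less Fcer1g and less Eomes, a transcription factor gene of effector and memory cells. Over both groups, 557 genes were higher and 441 lower of 11436 tested in edgeR with the library as a block. These counts were 5 and 1 without control replicate 1, 22 and 4 without control replicate 2, and 779 and 702 without butyrate replicate 1. Tcf7 was higher by 1.82 (SE 0.27, adjusted p = 0.0132) and Ccr7 by 1.49 (SE 0.31, adjusted p = 0.0262). BE692007 was higher by 1.53, Pik3ip1 by 1.30, Gbp2 by 1.29 and Ifi214 by 1.21. Fcer1g was at -1.001, Eomes at -0.74, and Hyou1 and Srm both at -0.68, while Gzmb did not pass (-0.52, adjusted p = 0.0537). Gzmd and Gzme were named by the rule, but their control levels were near 0, so no fold is given. Gzmd was at 0 and 1.72 CPM in control cells with Il7r and 7.46 and 10.2 CPM in those without.

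The groups were also tested alone, a choice made after the difference between them was seen. In control, 2213 genes were higher and 2350 lower in cells with Il7r, or 1397 and 1553 without control replicate 2. In butyrate, 499 were higher and 707 lower, or 253 and 314 without butyrate replicate 1 and 169 and 245 without butyrate replicate 2. Both groups passed for 906 genes, 850 in the same direction. Tcf7 was higher by 2.38 (SE 0.08) in control and 0.88 (SE 0.15) in butyrate, where it was 1.32 without butyrate replicate 1 and 0.35 without butyrate replicate 2 (adjusted p = 0.529). Ccr7 was higher by 2.34 and 0.63, the latter 0.48 without butyrate replicate 1 (adjusted p = 0.0505). Of 19 naive-state genes, 17 were higher and 0 lower in control, as adjusted over the list alone, and 9 and 0 in butyrate, or 10 and 0 adjusted over the list alone. Of 32 interferon genes, 29 were higher and 0 lower in control, or 31 and 0 adjusted over the list alone, against 9 and 0 in butyrate, or 14 and 1 adjusted over the list alone. Of cells with an Il7r UMI, 36.9 and 35.6% in control and 23.3 and 23.1% in butyrate were called G1, against 8.89 and 8.93% and 13.4 and 15.5% of cells without.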

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

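The tests of Il7r levels, of other cell types and of G1 shares had their bounds set before their values were seen. Tests of each group alone, the test of doublets, and the interval in the comparison with empty droplets were added after results were seen. What the test among G1 cells without Tcf7, Ccr7 or Id3 can decide was judged after its value was seen.

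The effect of butyrate differed between S or G2M cells and G1 cells by a test of the difference itself, with 2418 genes at a higher and 2236 at a lower value in S or G2M cells. Among named genes, the effect in S or G2M cells minus that in G1 cells was 1.75 for Il7r, 1.67 for Tcf7, 1.42 for S1pr1, 1.61 for Mxd4, 1.59 for Pik3ip1 and 1.88 for Ccng2. Aldoc was at 1.70 and Ifi206 at 0.77. It was negative for others, with -0.96 for Gzmb, -0.81 for Il2ra, -3.57 for Il24, -1.86 for Esm1 and -1.41 for Rrm2, an S phase gene whose list defined the classes. Il10 was at -1.77, and at -1.32 with an adjusted p of 0.155 without control replicate 2. Lta was at -0.71, at -1.15 without control replicate 1 and at -0.30 (adjusted p = 0.105) without control replicate 2. With a phase score limit of 0.1 the Gzmb difference was -0.46 (adjusted p = 0.0839).

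For Il7r, 3 technical explanations would have brought the difference of 1.75 below 0.88. It was 1.41 (SE 0.14) among deep cells thinned to 8000 UMIs and 1.34 (SE 0.07) with the phase score limit at 0.1. These values argue against depth and the score limit as the whole cause. It was 1.81 (SE 0.09) after free RNA was subtracted at an assumed 5% of each class sum. The true share was not measured, so this argues only against free RNA at about that share. Among G1 cells with no UMI of Tcf7, Ccr7 or Id3, Il7r was at -0.28 (SE 0.11, adjusted p = 0.0364), above the bound of -0.54. Transcripts of these genes were found in 55.9 and 51.3% of control and 19.2 and 18.8% of butyrate G1 cells, so the filter itself followed the treatment. Fewer such cells and lower levels within the same cells therefore cannot be told apart. The rise in S or G2M cells was not explained by a test.

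The differences between cells with and without an Il7r UMI also depended on the treatment, by a test of the difference itself. The variance of Il7r UMIs over their mean in thinned cells was 2.80 and 2.96 in control and 1.47 and 1.81 in butyrate. The butyrate values lie nearer to counting error alone, so the split may sort cells less well there. How much of the difference comes from this was not tested. Under butyrate the class effect was higher for 1316 and lower for 1153 genes, or 841 and 748 without control replicate 2 and 843 and 754 without butyrate replicate 1. Relative to control the effect changed by -1.51 for Tcf7, -1.71 for Ccr7, 0.84 for Gzmb and 0.96 for Srm. BE692007 was at -0.65, and did not pass at -0.46 without butyrate replicate 1. Pik3ip1 was at -0.75, and did not pass at -0.66 without butyrate replicate 2. Hyou1 was at 0.54, and did not pass at 0.44 without control replicate 1 and 0.45 without butyrate replicate 2. Gbp2 was at -0.39, at -0.74 without butyrate replicate 2, and did not pass at -0.32, -0.46 and -0.13 without control replicate 1, control replicate 2 and butyrate replicate 1. Ifi214 was at -0.55 and passed in no fit that left out 1 library, at -0.52 and -0.59 without control replicates 1 and 2 and -0.60 and -0.50 without butyrate replicates 1 and 2.

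Cells with Il7r were more often called G1, which could by itself separate the classes. In S or G2M cells of the control group alone, the slope of the log2 fold changes on those in all cells was 0.68, with 0.663 and 0.694 in the single libraries. The bound for G1 shares as the whole cause was under 0.5, which argues against cells called G1 as the whole cause. In these S or G2M cells, 1164 genes were higher and 1200 lower with Il7r. A slope below 1 leaves G1 shares a part. The S or G2M cells are also most of all cells, and the shared counts can raise the slope. Phase can still differ within S or G2M cells, so phase in general is not excluded.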

How the results depend on the processing

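The library-totals scaling, the equal weight per cell, the log2 limit of 1, each treatment group alone, mean Il7r UMIs, and the leave-outs, pairs and lower UMI limit of the quality values and of the Tcf7, Ccr7 or Id3 share were chosen after seeing the data. Genes higher and lower under butyrate were 1916 and 1951 with a mean of at least 20 CPM, 3198 and 3132 in G1 cells, 2847 and 2425 at a log2 fold change of at least 0.5, and 1768 and 774 at 1, where fewer genes can pass by construction. Leaving out 1 library gave 4367 to 4589 higher and 4310 to 4608 lower, with the lone library of a group assumed to vary like the other group. With an estimated correlation 0 of 14 lists passed, a setting with too few degrees of freedom to decide. In G1 cells, which were chosen by low S and G2M scores, the medians of the histone list (0.45) and the G2M list (0.34) reversed, as did Il7r (-1.08), Cdc20 (0.12), Cenpf (0.55), Cenpa (0.19), Usp1 (0.54) and Btg1 (-0.34), while 10 list or gene calls were lost, with G2M, Cdc20 and Cenpa among them, and 7 gained, with the histone list among them. With equal weight per cell Il7r reversed to -0.022. The Il7r share difference was 10.2 points without thinning, 1.00 at 4000 UMIs, -2.47 at 1000 UMIs with lower UMI limit, -1.77 for at least 2 UMIs and -0.0732 for mean UMIs. It was 2.15 and 5.20 within the pairs and 2.89 to 4.47 on leaving out 1 library. With a phase limit of 0.1 the differences in G1, S and G2M shares were 9.19, 5.92 and -15.1 points, and without thinning 9.14 for S and -9.95 for G2M. Within pairs they were -0.0967 and 2.24 for G1, 14.0 and 10.9 for S, and -13.9 and -13.1 for G2M. On leaving out 1 library they were 0.274 to 1.87, 11.5 to 13.4 and -13.8 to -13.2. Genes higher and lower with Il7r were 309 and 131 unthinned, 327 and 129 at 20 CPM, and from 5 to 779 and 1 to 702 on leaving out 1 library. In control 1473 were lower at 20 CPM, and leaving out 1 library gave 1397 to 2157 higher and 1553 to 2332 lower. In butyrate 433 were lower unthinned, where Gzmb reversed to 0.11, and leaving out 1 library gave 169 to 551 higher and 245 to 688 lower. The difference between groups then had 841 to 1009 higher and 748 to 964 lower. Phase class differences at a limit of 0.1 numbered 1638 and 2298. With all barcodes of at least 1000 UMIs the median depth differed by 6360.5 UMIs and the mitochondrial share by -1.62 points. On leaving out 1 library these were 2428.75 to 3727.75 and -0.971 to -0.774, and ribosomal shares 1.12 to 1.99. The share of cells with Tcf7, Ccr7 or Id3 at 1000 UMIs differed by -4.01 points, or -5.72 over all barcodes. Except where fewer genes or libraries were used, the cause was not tested. A mouse block ended the calls of Aldoc in all cells and in S or G2M cells, gained that of the NK list, and changed no other call of a named gene or tested list. Over all genes it lost 46 calls and added 256. The DESeq2 test, no count filter, subtracted free RNA and left-out doublet scores changed no call of a named gene and were not run on lists. Over all genes the DESeq2 test lost 1769 calls and added 42. No count filter lost 134 and added 250, subtracted free RNA 181 and 52, and left-out doublet scores 100 and 94. Most named genes were chosen for large changes or a small p, so their calls were less likely to be lost. DESeq2 size factors changed no call of a named gene or list.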

Other observations

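The bounds for cells of another type and for free RNA were set before their values were seen, while the interval for empty droplets and the test of doublets were added afterwards. A set of 10 genes from the dendritic, myeloid and CD4 T cell lists, chosen after their values were seen, rose under butyrate, although cells were sorted as CD8+Vα2+. They were H2-Aa, H2-Eb1, Cd74, Ciita, Itgax, Fscn1, Itgam, Cd68, Cd14 and Cd4. In G1 cells the myeloid and dendritic lists did not pass (medians 0.17 and 0.49). Cells of another type that lack Cd8a and Cd8b1 UMIs would put most of these UMIs in cells without Cd8a or Cd8b1. The bound against this also asked that the top 1% of cells hold under 50% of the UMIs of each gene. H2-Eb1, Itgam, Cd68, Fscn1 and Itgax met it, with 96.5% of 2631 UMIs in cells with Cd8a or Cd8b1 and 22.8% in the top 1%. The 96.5% lay near the share of all butyrate cells with a Cd8a or Cd8b1 UMI, 95.6 and 95.9%. As cells were sorted for CD8, the bound cannot decide about cells of another type that carry such UMIs. H2-Aa, Cd74, Cd14, Ciita and Cd4 did not meet the bound. Of their 619 UMIs, 97.1% lay in cells with Cd8a or Cd8b1, but the top 1% held 58.8%. Each except Cd74 was found in at most 2.29% of the cells of a butyrate library. At such shares the top 1% of cells hold a large part of the UMIs in any case, so this bound cannot decide. For all of them cells of another type stay open. Doublets of a T cell with another cell were expected to make up at most 2.13% of a butyrate library at these cell numbers. Shares of cells with a UMI of these 10 genes were taken without thinning, so the greater depth of butyrate cells can raise their excess over control. Cells with a Cd68 UMI made up 4.08 and 4.90% in control and 17.7 and 18.6% in butyrate. For H2-Eb1, Itgam, Cd68 and Fscn1 the excess over control, taken at its low 95% bound, was at least 2.54 points, which argues against doublets as the whole cause. For the other 6 genes it was as low as 0.526 points. H2-Aa, Cd14, Ciita and Cd4 were found in under 2.13% of cells in butyrate replicate 1, so they could not exceed that share. Leaving out the highest doublet scores moved H2-Aa from 3.95 to 3.91, Cd4 from 4.03 to 3.97 and Cd14 from 2.69 to 2.62. Cd74 went from 1.72 to 1.89, Ciita from 1.28 to 1.30 and Itgax from 1.18 to 1.15. Their rise thus did not rest on the cells with the highest scores, while other doublets stay open. Lyz2, abundant in myeloid cells, had 0 and 0 UMIs in control and 1 and 1 in butyrate. Free RNA would put the median log2 ratio of cells over empty droplets below -1. It was 0.31 over 10 genes (95% bootstrap interval -0.22 to 0.52). The interval does not exclude 0, which was the bound set against free RNA, but it excludes -1. Low expression of H2-Eb1, Itgam, Cd68 and Fscn1 by the T cells may remain as a hypothesis, found and tested on the same data.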
